A study of Homo sapiens with 4 samples.

How the data were processed

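Gene expression was measured by RNA sequencing in MDA-MB-231 cells, an established human triple-negative breast cancer line. Per the labels' protocols, the cells were grown with 10% fetal bovine serum and left for 24 h with or without the compound, and each library was built from 1.4 µg of total RNA with a kit for mRNA. The groups were DMSO, the solvent control, and Neoribocic, with 2 libraries in each. The sample names say Neoribocic while the treatment protocol uses the name Rib_CA, and both were read as the same treatment. The dose is not given in the sources used here. No label says that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

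The deposited values are raw counts per Ensembl gene, whole numbers with no normalization. The aligner, the counter, its handling of strand and overlapping genes, and the human build are not given in the sources used here. The submitters' processing notes name GRCm38 and mm10, which are mouse builds, although the table holds human Ensembl IDs, so no coordinates are given. Of 20263 gene IDs, 20148 were in the table of gene names used and 19761 had a symbol. In GENCODE release 29, 20224 were found and 19722 were protein-coding. Small counts were mostly even. Among counts below 20 the even share was 62.3% to 65.4%, against 50.2% to 51.1% among counts of 20 to 200. That is the pattern left when both mates of a read pair are counted, so counting precision may be lower than the totals imply. The totals were 34774542 and 37754168 counts for DMSO replicates 1 and 2, and 41572094 and 43014212 for Neoribocic replicates 1 and 2.

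Tests used edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group, libraries were scaled by TMM, and a robust quasi-likelihood model with the group as its only term was tested with glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change (Neoribocic minus DMSO) was its size divided by the square root of its F statistic. Levels are TMM-scaled CPM. For genes on fixed lists, counts of calls "adjusted over the list alone" are given beside those adjusted over all genes. Whole lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 3 and a preset inter-gene correlation of 0.01, adjusted over the 32 lists that had at least 5 tested members. Camera with an estimated correlation and fry were run beside it. With 4 libraries the estimated correlation leaves camera few residual degrees of freedom and so little power. Not passing with it does not decide whether a list moved, and the preset value in turn assumes little correlation.

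The design, the 35 gene lists, the fixed genes and the rule for naming genes were set before the data were examined. The named genes are 14 cell cycle genes fixed in advance, the 10 largest rises and 10 largest falls, and from each list up to 3 members per direction with the smallest p. A gene among the largest changes had to pass the threshold, have a mean of at least 5 CPM and a symbol, and have both Neoribocic libraries on the same side of both DMSO libraries. Of the list genes, 3 had no row. Some of the genes named by this rule, and 1 of the 14 lists past the camera threshold, are not reported here.

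The alternatives fixed in advance were RLE and upper-quartile size factors, library totals only, other count filters, DESeq2 1.42.0, limma-voom, edgeR without the robust option, the replicate number as a block, each library left out in turn, thinning to equal totals and a threshold of 0.01. Chosen after the data were examined were a correction for transcript length and GC content, leaving out the 13 mitochondrial genes, and halving all counts. The correction fitted a smooth surface of log2 CPM on length and GC content in each library (mgcv 1.9-3) and removed it. Length and GC content came from 1 GENCODE transcript per gene, the principal one and the longest where there were several. Exons shared by neighbouring genes were taken from the same annotation.

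The fit was tested on simulated counts for the comparison of Neoribocic with DMSO, with 200 changed genes among 13678 genes in the fit. It called 1 of 67 genes changed 1.5-fold, 22 of 67 changed 2-fold and 65 of 66 changed 4-fold, and 2 of its 90 calls were false. A shift of -1 planted in a list, in a test on 13675 genes with a planted length trend, was returned as a median of -0.99 without the correction and -0.97 with it. Camera then also called 2 lists with no planted shift without the correction and 0 with it. The planted trend followed length only, and the planted list shift did not depend on length. The test therefore cannot show how the correction treats a response that itself follows length or GC content. With so few changed genes, changes of 2-fold or less were thus often missed. In the data 5610 of 13879 genes were called, which loosens the Benjamini-Hochberg cutoff, so these rates of detection and of false calls do not carry over.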

Results

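Messenger RNA was profiled in MDA-MB-231 cells after 24 h with DMSO or with Neoribocic, a compound that the series title connects to a block of the cell cycle. Each group had 2 libraries, with totals of 34774542 to 43014212 counts. Replicates correlated at 0.977 (DMSO) and 0.982 (Neoribocic) on log2 CPM across genes, and libraries of different groups at 0.903 to 0.930; genes are not independent replicates. Scaled by library totals, replicate libraries differed by more than counting noise in 73.3% of genes for DMSO and 68.5% for Neoribocic, so none was a copy of another. Differences in composition, and counting of both mates, would raise these shares. The libraries differed in composition. Mitochondrial genes held 8.68% and 21.7% of counts in DMSO replicates 1 and 2, and 5.76% and 7.24% in Neoribocic replicates 1 and 2. Most markers of the line were high in all libraries, with VIM (vimentin) at 2804 to 4238 CPM, but CD274 (PD-L1) did not exceed 13.9 CPM or SPARC 1.01 CPM. Of the markers of other breast lines, CDH1 (E-cadherin) and ESR1 (the estrogen receptor) did not exceed 0.141 and 0.649 CPM, while KRT19 (keratin 19) reached 403 CPM and ERBB2 (HER2) 109 CPM.

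The comparison of Neoribocic with DMSO asks which genes the compound changes. With Neoribocic 23 of 36 G2/M and mitosis genes fell, 21 of 26 ATF4 and amino acid response genes rose, and 15 of 22 NF-kB and inflammatory cytokine genes rose. These lists passed camera (adjusted p = 7.38e-07, 1.06e-06 and 2.68e-06). With an estimated correlation, which leaves little power with so few libraries, each had a camera adjusted p = 0.469. MKI67 (ENSG00000148773), whose protein is the proliferation marker Ki-67, fell from 1485 ± 55.7 to 110 ± 15.5 CPM (SD, n = 2 per group), a log2 fold change of -3.76 ± 0.22 (SE). CENPE and CENPF, which encode kinetochore proteins, fell by 3.87 and 3.76 on the log2 scale, the scale of all rises and falls given without a unit. IL24, a cytokine gene, rose from 0.445 ± 0.190 to 13.4 ± 0.783 CPM, and CHAC1, a glutathione-degrading enzyme induced through ATF4, rose by 3.95 ± 0.39. In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 5610 of 13879 genes, 2650 higher and 2960 lower.

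Of these, 3706 changed at least 2-fold, 1656 upward and 2050 downward. In 10421 genes both Neoribocic libraries lay on the same side of both DMSO libraries, where chance alone gives 33.3% of genes. The share of calls that were higher was 47.2% with TMM, 56.8% with upper-quartile factors and 59.6% with library totals, scalings that moved the median log2 fold change by 0.12 and 0.17. Without Neoribocic replicate 1 the test called 2468 genes, and without DMSO replicate 1 or 2 the higher calls numbered 1718 and 1671.

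Log2 fold changes followed transcript length and GC content. Across 13862 genes the Spearman correlation was -0.40 with length and 0.45 with GC content, and the median log2 fold change ran from 0.73 in the 10% of genes with the shortest transcripts to -0.71 in the 10% with the longest. The 2 Neoribocic libraries differed along the same properties, replicate 2 minus replicate 1 correlating at 0.42 with length and -0.51 with GC content. A median corrected for both properties is therefore given for each gene list below that was tested with camera, and a corrected log2 fold change for the genes below that it moved by over 1.5 times. With the correction, chosen after the data were examined, 5120 genes were called and 3496 of the 5610 kept their call and direction.

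**Figure D1:**
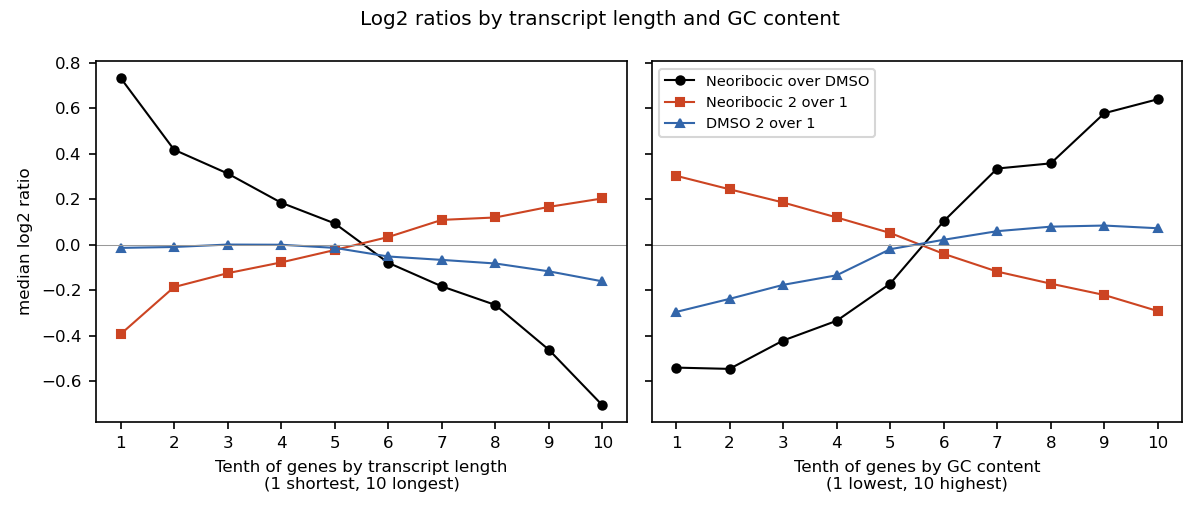
Median log2 ratio (vertical axis) of genes in 10 bins of near-equal size by transcript length (left) and by GC content (right), for Neoribocic over DMSO (black), Neoribocic replicate 2 over 1 (red) and DMSO replicate 2 over 1 (blue). The black line runs from 0.73 to -0.71 with length and from -0.54 to 0.64 with GC content, and the red line slopes the other way in both panels.

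Of the 14 cell cycle genes fixed in advance, 7 fell, 1 rose and 6 did not pass the threshold. CCNE2 (ENSG00000175305), the E-type cyclin of S phase entry, fell by 2.58 (SE 0.23; edgeR adjusted p = 5.74e-04). CDK6 (ENSG00000105810), a kinase that phosphorylates RB at the G1 to S transition, fell from 81.2 ± 21.1 to 26.7 ± 7.58 CPM, whereas its relative CDK4 (ENSG00000135446) rose from 58.9 ± 0.622 to 113 ± 22.8 CPM. Their log2 fold changes were -1.60 ± 0.28 and 0.94 ± 0.21, with edgeR adjusted p = 0.00386 and 0.00976. The correction brought CDK6 to -0.57 and CDK4 to 0.61 (edgeR adjusted p = 0.0429 and 0.0230). Of the exon bases of CCNE2 37.05%, and of those of CDK4 43.2%, overlap a gene on the opposite strand. For CDK4 the edgeR adjusted p ran from 5.48e-04 to 0.0801 over the alternatives, the highest and the only one above 0.05 being without Neoribocic replicate 1. CCNA2, the cyclin of S phase and G2, fell by 1.53, RB1 by 1.34 (corrected -0.67), CDK1 by 0.91 and CCND1 (cyclin D1) by 0.83. The calls of CCND1 and CDK1 were lost without Neoribocic replicate 1, at edgeR adjusted p = 0.104 and 0.0561, and that of CCND1 also without DMSO replicate 2, at 0.0558; the lowest values over the alternatives were 9.91e-04 and 2.46e-04. CDKN1A, the gene of the CDK inhibitor p21, stood at 0.91 ± 0.32 with an edgeR adjusted p of 0.0548, and over the alternatives the adjusted p ran from 0.00668 to 0.388, the lowest with the replicate number as a block. It was also below 0.05 with DESeq2 (0.0221), limma-voom (0.0463), upper-quartile factors (0.0240), library totals (0.0347), both other count filters (0.0444 and 0.0478) and halved counts (0.0492), and without DMSO replicate 1 (0.0165), while the correction brought CDKN1A to 0.40. CCNB1 was at -0.48 ± 0.20 (corrected -0.22), E2F1 at -0.54 ± 0.23, CDKN1B at 0.36 ± 0.21 and CCND3 at -0.34 ± 0.22. With the correction E2F1 was at -1.10 and CCND3 at -0.94, both past the edgeR threshold (adjusted p = 0.00433 and 0.00531). MYC was at 0.30 ± 0.63, with a wide spread in DMSO (18.6 ± 15.1 CPM), at -0.44 with the correction, at -0.36 without DMSO replicate 1 and at 1.53 without DMSO replicate 2, where it passed (edgeR adjusted p = 0.0154).

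**Figure D2:**
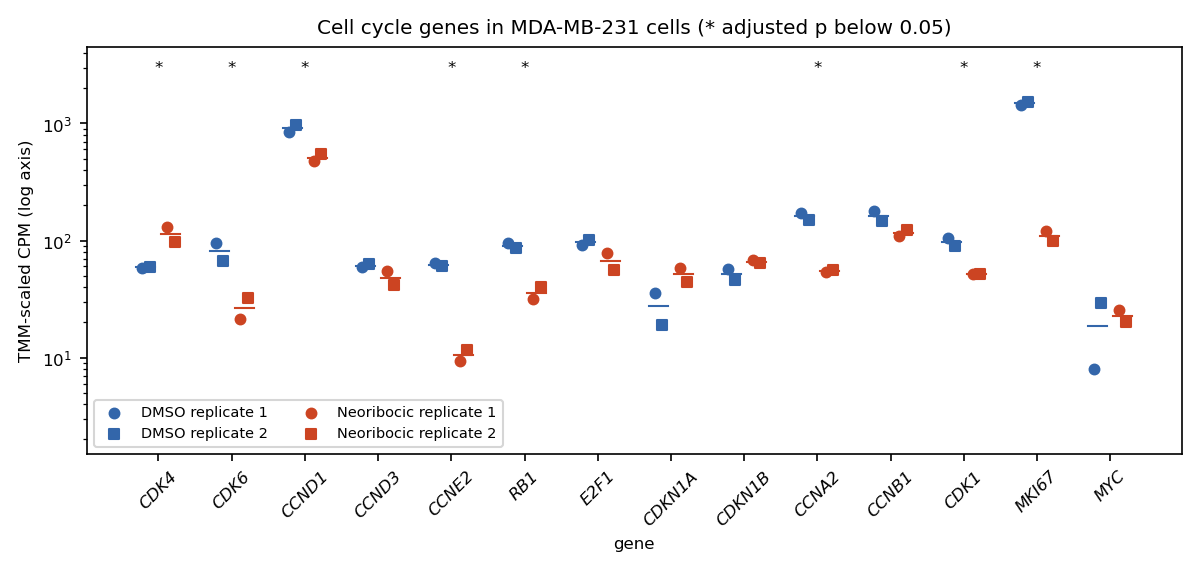
TMM-scaled CPM (log axis) of the 14 cell cycle genes fixed in advance, with 1 point per library, bars at group means, DMSO in blue and Neoribocic in red; stars mark adjusted p below 0.05 in edgeR. MKI67 lies at 1485 CPM on average in DMSO and at 110 CPM in Neoribocic, and CDK4 is the starred gene with the higher mean in Neoribocic.

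The list of E2F targets and G1/S genes had 23 of 30 members lower and 0 higher, with 23 also lower when adjusted over the list alone. Its median log2 fold change was -1.10 (corrected -0.99), and its camera adjusted p was 7.38e-07, against an adjusted p = 0.469 with an estimated correlation. Besides CCNE2 and CCNA2 it included ATAD2, a chromatin-binding E2F target that fell by 2.27 ± 0.23 (corrected -1.48). In the list of DNA replication machinery 13 of 30 genes fell and 0 rose, or 14 and 0 adjusted over the list alone, with a median of -0.53 (corrected -0.64). The camera adjusted p was 9.24e-05, against an adjusted p = 0.469 with an estimated correlation. MCM6 and MCM4, subunits of the replicative helicase, fell by 2.28 and 1.87, and POLA1, the catalytic subunit of DNA polymerase alpha, by 2.95 ± 0.29. Among G2/M and mitosis genes 23 of 36 fell and 1 rose, as they did adjusted over the list alone, with a median of -1.36 (corrected -0.99). Camera gave this list an adjusted p of 7.38e-07, against an adjusted p = 0.469 with an estimated correlation. The gene that rose was CENPA, the centromeric histone H3 variant, at 0.84 ± 0.25. Its call was lost without DMSO replicate 2 or without Neoribocic replicate 1, at edgeR adjusted p = 0.124 and 0.162, with 0.00911 the lowest over the alternatives.

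Genes of homologous recombination and the Fanconi pathway were lower in 13 of 20 cases and higher in 0, or 14 and 1 adjusted over the list alone. The median was -1.06, or -0.55 corrected, with a camera adjusted p = 1.12e-04 and an adjusted p = 0.470 with an estimated correlation. BRCA1 and BRCA2 fell by 2.02 and 2.47 (corrected -1.18 and -1.47), and RBBP8, which encodes the end-resection factor CtIP, by 2.12. Among CDK, cyclin and pocket protein genes 5 of 23 rose and 7 fell, or 6 and 7 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.361; median -0.34, corrected -0.22). CDKN2D, an inhibitor of CDK4 and CDK6, rose by 1.83 (corrected 1.0) and CDK9, a kinase of transcription elongation, by 1.04.

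The list of ATF4 and amino acid response genes had 21 of 26 members higher and 2 lower, or 22 and 2 adjusted over the list alone. Its median was 1.22 (corrected 1.13), with a camera adjusted p = 1.06e-06 and an adjusted p = 0.469 with an estimated correlation. SESN2, a stress-induced inhibitor of mTORC1 signalling, rose by 3.09 ± 0.22, from 13.5 ± 0.496 to 115 ± 13.6 CPM. PCK2, the mitochondrial PEP carboxykinase, rose by 2.59 and the transcription factor CEBPB by 2.16. The members that fell were ATF5, a transcription factor of the same stress response, at -1.69 ± 0.45 with 21.2% of exon bases overlapped on the opposite strand, and the lipoprotein receptor gene VLDLR, at -0.60 ± 0.21. Over the alternatives the adjusted p of ATF5 ran from 3.42e-04 to 0.164 and that of VLDLR from 0.0222 to 0.246. ATF5 lost its call without DMSO replicate 2 (0.0536) or either Neoribocic library (0.164 and 0.132), VLDLR lost it when any of the 4 libraries was left out (0.0889 to 0.198), and VLDLR stood at 0.33 after the correction.

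NF-kB and inflammatory cytokine genes rose in 15 of 22 cases and fell in 0, also when adjusted over the list alone, with a median of 1.69 (corrected 1.44). The camera adjusted p was 2.68e-06, against an adjusted p = 0.469 with an estimated correlation. IL1B and IL1A, the interleukin 1 genes, rose by 2.91 ± 0.28 and 2.79 ± 0.30 from low levels of 2.08 and 1.30 CPM. Both also belong to the list of senescence-associated secretory genes, where 10 of 19 rose and 2 fell, as they did adjusted over the list alone, with a median of 0.75 (corrected 0.71). Its camera adjusted p was 0.0213, against an adjusted p = 0.670 with an estimated correlation. The call was lost without DMSO replicate 1 (0.0949), with fry (0.107) and with the correction (0.111). IGFBP3, a binding protein of insulin-like growth factors, fell by 1.65, and VEGFC, a lymphangiogenic growth factor, by 0.74, a call lost without DMSO replicate 2 or Neoribocic replicate 1 or 2 (edgeR adjusted p = 0.140, 0.139 and 0.0757).

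Among NRF2 target genes 10 of 22 rose and 0 fell, also adjusted over the list alone, with a median of 0.61 (corrected 0.53). Camera gave this list an adjusted p of 0.0148, against an adjusted p = 0.469 with an estimated correlation. HMOX1, the heme oxygenase gene, rose by 2.65 and OSGIN1, an oxidative stress gene, by 1.75 (corrected 1.13).

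Lysosome and autophagy genes rose in 11 of 28 cases and fell in 0, or 12 and 0 adjusted over the list alone, with a median of 0.50 (corrected 0.42). The camera adjusted p was 0.00641, against an adjusted p = 0.470 with an estimated correlation and a camera adjusted p = 0.0541 after the correction. MAP1LC3B, the autophagosome marker LC3B, rose by 1.48, and TFE3, a transcription factor of lysosomal genes, rose from 172 ± 8.81 to 394 ± 21.8 CPM. Nuclear genes of the mitochondrial respiratory chain rose in 13 of 24 cases and fell in 2, or 15 and 2 adjusted over the list alone, with a median of 0.72 (corrected 0.35). Camera gave this list an adjusted p of 0.0107, against an adjusted p = 0.670 with an estimated correlation. It was 0.0586 without DMSO replicate 2, the library in which mitochondrial genes held 21.7% of counts, and fry gave 0.147. The complex I genes NDUFB8 and NDUFV1 rose by 1.72 and 1.47 (corrected 0.66 and 0.98), NDUFB8 sharing 33.8% of its exon bases with another gene on its strand, while UQCRC2 of complex III and NDUFA9 of complex I fell by 0.69 and 0.63. Over the alternatives the adjusted p of UQCRC2 ran from 0.0280 to 0.242 and that of NDUFA9 from 0.0220 to 0.272, and NDUFA9 stood at 0.24 after the correction. UQCRC2 lost its call without DMSO replicate 1 or either Neoribocic library (0.242, 0.215 and 0.0907) and with the correction (-0.45, adjusted p = 0.104), and NDUFA9 when any of the 4 libraries was left out (0.0641 to 0.185).

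Heat shock response genes fell in 10 of 17 cases and rose in 0, also adjusted over the list alone, with a median of -0.67 (corrected -0.90). The camera adjusted p was 0.00157, against an adjusted p = 0.469 with an estimated correlation. HSP90AA1, the inducible HSP90 chaperone, fell from 3147 ± 775 to 631 ± 69.8 CPM, HSPH1, a large HSP70 relative, fell by 2.37 and the co-chaperone gene DNAJA1 from 433 ± 38.8 to 111 ± 9.56 CPM. YAP/TEAD target genes fell in 13 of 20 cases and rose in 0, also adjusted over the list alone, with a median of -0.93 (corrected -0.71). Camera gave this list an adjusted p of 9.09e-04, against an adjusted p = 0.469 with an estimated correlation. TGFB2, a TGF-beta ligand gene, fell by 3.07 ± 0.23, MYOF (myoferlin) by 1.68 (corrected -1.11) and ANKRD1 by 1.54. Fatty acid synthesis genes fell in 5 of 14 cases and rose in 0, or 4 and 0 adjusted over the list alone, with a median of -0.55 (corrected -0.06). The camera adjusted p was 0.0440, against an adjusted p = 0.469 with an estimated correlation. The call was also lost without DMSO replicate 2 (0.0586), Neoribocic replicate 1 (0.0669) or replicate 2 (0.0570), with library totals (0.0583), the CPM filter (0.0553), the replicate block (0.0579) and the correction (0.256). ACSL3, a fatty acyl-CoA synthetase, fell by 1.62 and ACACA, which makes malonyl-CoA, by 1.33 (corrected -0.87 and -0.69).

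**Figure D3:**
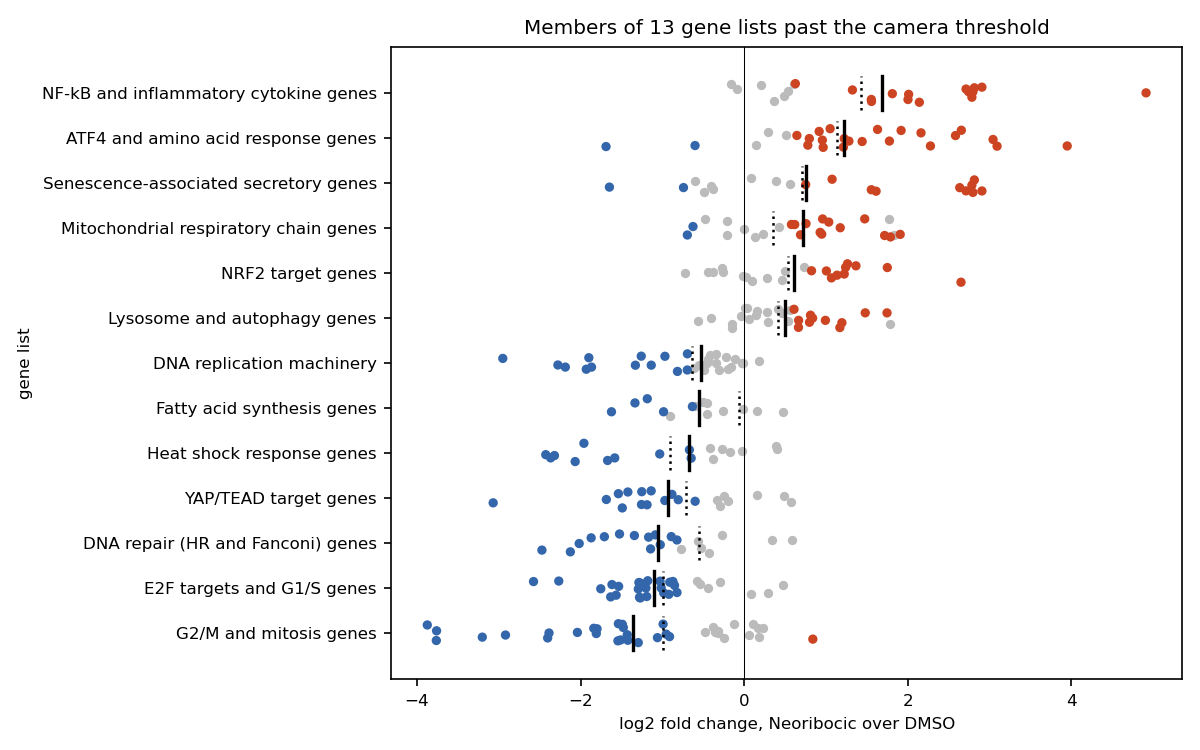
Log2 fold change, Neoribocic over DMSO (horizontal axis), of each tested member of 13 of the 14 gene lists past the camera threshold (vertical axis), in red or blue where a gene rose or fell in edgeR and in grey where it did not pass. Solid bars are list medians and dotted bars medians after length and GC correction; they run from -1.36 for G2/M genes to 1.69 for NF-kB genes, and the fatty acid list moves from -0.55 to -0.06.

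The lists that follow did not pass camera. Interferon response genes fell in 13 of 27 cases and rose in 4, also adjusted over the list alone (camera adjusted p = 0.0861). The list passed without DMSO replicate 1 (0.0404), without Neoribocic replicate 1 (0.0322) and after the correction (0.00403). IFIT3, an interferon-induced antiviral gene, fell by 2.68 and RIGI, the viral RNA sensor, by 2.17, while IRF7 rose by 1.98 (corrected 1.30). Antigen presentation genes rose in 6 of 17 cases and fell in 2, or 7 and 2 adjusted over the list alone (0.165). HLA-B rose by 1.53 (corrected 0.81) and HLA-E by 1.39; reads of these closely related genes can be divided among copies. Among unfolded protein response chaperones 6 of 20 rose and 2 fell, also over the list alone (0.213). ERN1, the stress sensor IRE1, rose from 18.1 ± 0.231 to 70.5 ± 5.65 CPM. Among apoptosis regulators 5 of 25 rose and 3 fell, also over the list alone (0.244), with the death receptor genes TNFRSF10B and TNFRSF10A up by 1.67 and 1.12. Of 27 immediate early and MAPK feedback genes 10 rose and 2 fell, also over the list alone (0.213, or 0.0187 without DMSO replicate 2), led by the phosphatase gene DUSP1 at 2.14. Of 22 hypoxia and glycolysis genes 5 rose and 3 fell, also over the list alone (0.940). Their median was -0.17 while camera pointed upward, and the correction turned it to 0.25. VEGFA rose by 1.42 (corrected 0.77) and HIF1A fell by 1.40 (corrected -0.81). The medians of the other lists in this paragraph were -0.88 (corrected -0.59) for interferon, 0.80 (0.16) for antigen presentation, 0.35 (0.24) for unfolded protein response, 0.18 (0.39) for apoptosis and 0.30 (0.22) for immediate early genes.

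Mesenchymal genes fell in 6 of 17 cases and rose in 2 (camera adjusted p = 0.213, or 0.0343 without DMSO replicate 1), and epithelial genes rose in 6 of 17 and fell in 4 (0.221), with the same counts adjusted over the list alone. SNAI2, the transcription factor Slug, fell by 3.05 ± 0.43 and FN1 (fibronectin) by 1.15 (corrected -0.70), while ITGA5, the integrin that binds it, rose by 1.36. The claudin genes CLDN1, CLDN7 and CLDN4 rose by 1.97, 1.88 (corrected 1.27) and 1.32, while the junction genes TJP1 and DSP fell, TJP1 by 2.28 (corrected -1.51) and DSP from 231 ± 6.89 to 57.9 ± 2.07 CPM, a log2 fold change of -2.00 (corrected -1.31). Of 28 TGF-beta and extracellular matrix genes 3 rose and 7 fell (0.291), and of 13 luminal and hormone receptor genes 3 rose and 6 fell (0.529), also over the list alone. Of 26 ribosome biogenesis and MYC target genes 3 rose and 9 fell, also over the list alone (0.456, or 0.0315 after the correction), with UTP20, a factor of small subunit assembly, at -3.46 ± 0.24. Cholesterol and sterol synthesis genes rose in 4 of 24 cases and fell in 1, or 0 and 1 adjusted over the list alone (0.958), with a median of -0.04 against an upward camera direction. In the list of metallothionein genes, which also holds the zinc transporter gene SLC30A1, 3 of 5 rose and 1 fell, or 4 and 1 over the list alone (0.130), with a corrected median of 0.06 against 1.24. Those that rose were the metallothioneins MT1X, MT2A and MT1E, by 1.53, 1.2 and 1.24, near-identical genes that can share reads; the correction brought them to 0.38, 0.08 and 0.06 and ended each call (edgeR adjusted p = 0.142, 0.720 and 0.823). MT1E also lost its call without DMSO replicate 1 or 2 or Neoribocic replicate 1 (0.0708, 0.114 and 0.0865). SLC30A1 fell by 0.82, a call lost with library totals (0.0955), with the correction (-0.08, adjusted p = 0.779) and without DMSO replicate 2 or Neoribocic replicate 1 (0.0855 and 0.115). Xenobiotic metabolism and AHR genes rose in 3 of 14 cases and fell in 2 (0.336), and replication-dependent histone genes rose in 2 of 12 and fell in 0 (0.220), also over the list alone. The histone list held 20 genes, of which only these 12 were tested. Those that rose had low levels, H3C10 from 0.280 to 1.45 CPM and H1-2 from 6.68 to 14.8 CPM, so the list says little about histone RNA. Medians were -0.58 (corrected -0.47) for mesenchymal, 0.50 (0.00) for epithelial, -0.34 (-0.29) for TGF-beta and matrix, and -0.76 (-0.52) for luminal genes. Those of ribosome biogenesis genes were 0.00 (-0.31), of xenobiotic genes 0.30 (0.26) and of histone genes 0.24, turned to -0.14 by the correction, while cholesterol genes had a corrected median of 0.00. Fry, which tests whether a list's genes move one way on balance, passed for interferon, apoptosis, unfolded protein response, luminal and ribosome biogenesis genes (adjusted p = 0.0327, 0.0327, 0.0327, 0.0298 and 0.0239).

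Markers of the line itself rose in 2 of 14 cases and fell in 5, also over the list alone (camera adjusted p = 0.203; median -0.44, corrected -0.11). EGFR, the epidermal growth factor receptor, fell by 1.47 (corrected -0.76) from 999 ± 114 CPM, and CAV1 (caveolin 1) by 1.42. Markers of other breast lines rose in 1 of 7 cases and fell in 2, also over the list alone (0.958), with a median of 0.03 (corrected -0.19) against a downward camera direction. Of the fibroblast markers 4 were tested and ACTA2 rose from 2.77 ± 1.13 to 7.98 ± 0.801 CPM, a call lost without Neoribocic replicate 1 (edgeR adjusted p = 0.0652). Of the kidney markers 2 were tested and WT1 fell from 0.684 CPM, a call lost without DMSO replicate 1 or either Neoribocic library (0.0610, 0.108 and 0.0675). Of the blood markers 4 were tested and 0 passed edgeR's threshold. CD68, which many cell types express, reached 340 CPM, and the other blood markers stayed at or below 0.959 CPM.

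The largest rises included genes whose exons lie largely within other genes on the same strand, so that their counts are uncertain. TMEM265 (100% of exon bases shared) rose by 5.63, and the read-through genes MICOS10-NBL1, PTGES3L-AARSD1 and TMEM256-PLSCR3 rose by 4.87, 3.84 and 3.49. The last of these lost its call without Neoribocic replicate 1, at an edgeR adjusted p of 0.0816. Without such overlap were GUCA1B at 3.79 and C15orf48 at 3.48; BCL2L2, a BCL2 relative that shares a small part of its exons, rose by 3.24. The other genes with the largest falls were FAM111B at -3.76 ± 0.55, the utrophin gene UTRN at -3.67, SERTAD4 at -3.66, NRK at -3.59, SAMD9 at -3.49 and KLHL4 at -3.47. Among the 10 largest falls, CENPE, CENPF, MKI67, UTRN, NRK and UTP20 had transcripts of 8062 to 12678 bases. They lie in the 10% of genes with the longest transcripts, whose median log2 fold change was -0.71. As differences of corrected log2 CPM, all 10 falls were smaller, between -3.26 (FAM111B) and -2.52 (NRK).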

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

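Chosen only after the data were examined were the length and GC correction, the fit without mitochondrial genes and the halved counts. The 10 planned settings that kept all libraries and the 0.05 threshold called 5317 to 5974 genes, and 143 to 153 of the 153 called named genes held in them, against 108 (without Neoribocic replicate 1) to 133 with a library left out and 125 after the correction, which lost 23 and reversed 5. With each library left out in turn the test called 2468 to 4536 genes, 1001 to 2215 higher and 1467 to 2382 lower, and 2267 to 3937 at least 2-fold; the lone library of a group is then assumed to vary like the others. The lowest of each range came without Neoribocic replicate 1; higher calls numbered 1718 and 1671 without DMSO replicates 1 and 2. Fewer libraries are part of this by construction. A threshold of 0.01 left 2883 genes. After the correction 2449 genes changed at least 2-fold and 184 of the 5610 main calls had the opposite sign; the cause was not tested. No label ties equal replicate numbers, whose libraries' deviations from group means correlated at -0.05; with the replicate number as a block 5594 genes were called, 5219 of them shared with the main test. Of 168 pairs of a called list and a setting, 141 held, 0 changed direction, 14 were lost with an estimated correlation, which left 0 lists, and 13 were lost otherwise. The test with an estimated correlation had little power with so few libraries.

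Among genes, MYC turned to -0.36 without DMSO replicate 1 (1.53 and called without DMSO replicate 2) and -0.44 with the correction, which also turned VLDLR to 0.33, ISG15 to -0.15, TIMP1 to -0.073, NDUFA9 to 0.24 and GSTP1 to -0.23. Lists that did not pass in the main test and pointed the other way, with adjusted p, were cholesterol with fry (0.878), without DMSO replicate 1 (0.504) or Neoribocic replicate 1 (0.951) and with the correction (0.801), hypoxia without DMSO replicate 1 (0.851), histone genes with the correction (0.453), and other breast line markers without DMSO replicate 1 (0.879) or 2 (0.823). With each library left out these p ranged from 0.499 to 0.951 for cholesterol, 0.813 to 0.907 for hypoxia and 0.692 to 0.961 for other breast line markers. The cause was not tested. Thinning to equal totals left 5563 calls and halving the counts 5670, so the unequal totals moved the count little. Thinning went only down to the 34774542 counts of DMSO replicate 1, and halving added no sampling noise. Neither can show how a much lower depth would act. Of the 5610 calls 3706 were of at least 2-fold, so smaller changes were called too. Changes of 2-fold or less were often missed only in simulated counts with few changed genes.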

Other observations

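Chosen after the data were examined were all gene families below and the tests of library bias, of matched lists and of length within the G2/M list. With an estimated correlation the camera adjusted p of the 11 families lay between 0.572 and 0.883, so 0 passed, in a test with little power here. Among all 13879 tested genes 2960 fell and 2650 rose, the background against which the counts per family are to be read. Genes of cohesin, condensin and the related SMC5/6 complex, which hold, compact and maintain chromosomes, fell in 17 of 18 cases, with a median log2 fold change of -1.94 (corrected -1.27). SMC3 and SMC4 fell by 2.64 and 2.63. Nucleoporin genes fell in 14 of 23 cases (median -1.01, corrected -0.42), with TPR at -3.44, and kinesin genes fell in 16 of 30 and rose in 2 (median -1.10, corrected -0.76). Genes of cytosolic ribosomal proteins rose in 41 of 77 cases and fell in 0, with a median of 1.0 (corrected 0.27); a first definition of this family, with paralogs and without RPLP and RPSA genes, gave 39 of 80. These genes held 3.42% and 2.58% of counts in DMSO and 7.68% and 4.80% in Neoribocic. Complex I genes rose in 17 of 35 cases and fell in 1 (median 1.02, corrected 0.24), and mitochondrial ribosomal protein genes rose in 24 of 75 and fell in 5 (median 0.46, corrected 0.16; camera adjusted p = 0.00193, or 0.414 corrected and 0.625 with an estimated correlation). The mitochondrially encoded genes fell in 4 of 13 cases (median -1.48, corrected -1.69), with the 2 DMSO libraries far apart in these genes. Selenoprotein genes rose in 5 of 11 cases, SELENOW by 2.88 (corrected 1.93) and SELENOM by 2.24 (corrected 1.23), and protocadherin genes fell in 13 of 49 and rose in 2. Their medians were 0.51 (corrected 0.54) and -0.83 (corrected -0.53). Proteasome genes rose in 8 of 37 and fell in 7, with no camera call (adjusted p = 0.231) and a median that the correction turned from 0.30 to -0.05. ZNF genes rose in 54 of 452 and fell in 73, with a median of -0.09 and no camera call (0.585), but the correction turned the median to 0.26 and camera then passed upward (0.0334).

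MAP2K6, a kinase of the p38 pathway, had 60 and 57 counts in DMSO and 0 in both Neoribocic libraries, and was singled out after its values were seen. It shares no exon bases with another gene on its strand. The other 2 genes with 0 counts in 1 group and at least 50 in each library of the other went the opposite way, ENSG00000260272 with 805 and 1379 counts and ENSG00000100101 with 439 and 127 in Neoribocic replicates 1 and 2 and 0 in both DMSO libraries. They share 99.9% and 100% of their exon bases with other genes on the same strand, so these counts may come from how shared reads were assigned.

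Log2 fold changes fell with transcript length and rose with GC content. They also fell with genomic span, at a Spearman correlation of -0.43. With the other properties held fixed, the rank correlations were -0.20 for span, -0.19 for length and 0.31 for GC content. If genomic span were the whole cause, the 10% of genes with the shortest span should show little relation to GC content. The Spearman correlation there was 0.246 (value 0.2455, 95% interval 0.193 to 0.295 from resampling genes). The interval does not measure the spread between samples, and its low end lies slightly below the bound set for arguing against span. The correlation itself argues against span as the whole cause but not as part of it. Library bias is a candidate explanation, since the 2 Neoribocic libraries, replicate 2 minus 1, differed along the fitted trend at -0.5807. The 2 DMSO libraries differed along it at 0.258, which a stronger response to the compound cannot produce. For the Neoribocic libraries a stronger response in replicate 1 remains open. After correction their difference still correlated at -0.1888 with the log2 fold change, between the bounds set for either answer. An effect of the compound on long or AT-rich transcripts was not tested.

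The proliferation lists were lower with Neoribocic, and length and GC content could produce such a fall. Among 10000 random lists matched on length, GC content and level, the share with a median as low was 0.0001 for E2F targets and for G2/M genes, the smallest these lists can give, which argues against the trend as the whole cause. Part of the G2/M fall may follow length, since log2 fold change and length correlated at -0.758 within that list. The 18 shorter genes had a median of -0.37 (corrected -0.62) with 7 lower, and the 18 longer ones -1.82 (corrected -1.29) with 16 lower. A block of the cell cycle by the compound, which the series title names, stays open as a hypothesis. The proliferation lists bear on it only through RNA levels, and DNA content or cell counts, which could decide it, were not analysed here.

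Read-through and fully overlapped genes were among the largest rises. Division of reads among overlapping genes is a candidate explanation: between replicates, the SD of log2 differences of the 204 overlapped genes was 2.60 times that of level-matched genes in DMSO and 3.04 times in Neoribocic. Between the groups that ratio was 1.31. The spread between replicates shows that such counts vary more, not why a gene rose in both Neoribocic libraries. MICOS10-NBL1, with 83.4% of exon bases shared, fell short of the bound for these 204. A fixed pool of reads divided anew would lower the component genes. In edgeR, PTGES3L and TMEM256 rose by 2.20 and 2.08, PTGES3L from a low mean of 0.340 CPM in DMSO to 1.57 CPM in Neoribocic. MICOS10, NBL1, AARSD1 and PLSCR3 were not called, at 0.68, -0.24, -0.09 and -0.01. A general rise of read-through RNA would lift all read-through genes. The 74 read-through genes exceeded matched genes by 0.08 only (value 0.08166, interval -0.31 to 0.37 from resampling genes, not samples), with 12 higher and 8 lower. An effect on single read-through genes was not tested.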
